A study of Triticum aestivum with 72 samples.

How the data were processed

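Small RNAs were profiled in leaves of the wheat (Triticum aestivum) cultivars Akteur, Fengyou and Svitava, infected with wheat dwarf virus (WDV) or not inoculated. Per the labels' protocols, leaves were flash-frozen, RNA was extracted with Trizol, and libraries were built with a Lexogen kit for Illumina sequencing. The authors deposited a table of raw read counts with 2237 features in 72 columns, and the counts are whole numbers with no normalization. Features carry the names of mature miRNAs from many plant and animal species, and 273 of them carry the joined names of several miRNAs. The submitters' processing notes name Bowtie2 and the mouse build mm8. How reads were trimmed, what they were aligned to for this table, and how reads that match several names were counted is not given in the sources used here. No sequences and no wheat genome were used here, so features are given by name without genome positions, and a name from another species states only which entry the authors counted the reads under.

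The 72 columns were 18 libraries with 4 columns each, 3 libraries in each of 6 groups of cultivar and treatment. The 4 columns of a library share the number after the cultivar name and the sheet number in the titles and were taken as repeat runs (lanes) of 1 library. The counts of its lanes differed by about the sampling noise (chi-square per degree of freedom 0.844 to 1.213, with 5 of 18 libraries at p under 0.05), whereas libraries of a group differed far more (21.2 to 96.9). The 4 lanes were therefore summed and counted as 1 library, and the replicate is the library, with n = 3 per group. All columns were used. The labels do not say that libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may in part be technical.

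Library totals ran from 46951 to 197652 counts, so 1 count was worth 5.06 to 21.3 CPM (counts scaled to the same total in every library), and a floor of 3 counts in 1 library stood for 15.2 to 63.9 CPM. The median feature had a total of 1 count over all libraries, and 377 features reached a total of 10 or more. CPM values of single features in groups were computed from the deposited counts with TMM-scaled library sizes, while shares of reads, the summed CPM of the copper-protein features and the values of 1 and 3 counts used total counts. Levels are given as mean ± SD over the 3 libraries of a group. Intervals (exact binomial, 95%) and floors cover counting error only, since PCR copies were not separated from independent molecules.

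The test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit) with Benjamini-Hochberg adjustment over all features tested and a call at an adjusted p under 0.05. All 18 libraries were fitted with 1 mean per group after TMM scaling and edgeR's filter on low counts, which kept 190 features holding 99.5% of the counts. Contrasts were WDV against non-inoculated in each cultivar, the mean of these over the 3 cultivars, their difference between cultivars, and each pair of cultivars within a treatment. Log2 fold changes are edgeR's, and their standard error (SE) was taken as the absolute log2 fold change over the square root of F. Where every library of a group had 0 counts, a lower bound of the fold was computed against 3 counts over the whole group. Where a group had 1 to 3 counts, the ratio is given with its counting interval. Values per library, such as total counts, were compared by exact two-sided permutation of treatments within cultivars. Within 1 cultivar the smallest p that 3 against 3 libraries can give is 0.1.

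A total of 11 lists of miRNA families was fixed before the data were examined, as were the samples' groups, the tests, the alternatives below and the rule for naming features. The lists were families linked to the RNA silencing machinery, NLR resistance genes, virus infection in rice (the antiviral list) and auxin signalling. Others were linked to developmental transcription factors, copper proteins, and phosphate and sulfate metabolism. Members of the antiviral list were not sorted by whether they help or hinder a virus. Further lists were repeat-related wheat miRNAs and miRNAs with names in the style used for animals (a sign of RNA from another source). The last 2 were structural RNA fragments (a sign of degraded RNA) and viral features, with WDV, virus or viral in the name. No feature fell in the last 2 lists, and part of the miRNAs named after animal viruses, 2 of them tested, were counted with the animal-style names because their names have the same form. Lists were tested in the 4 WDV contrasts with fry (limma 3.58.1), whose p tests whether the members move on balance in 1 direction, and whose mixed p tests for change in either direction. The same lists were tested with camera at a preset correlation of 0.01 and at a correlation estimated from the data. Camera tests whether members change more than the other features do, which is a different question from that of fry. Values given with an estimated correlation are from camera. Adjustment was over all list tests of a method. Members of several lists overlap, with 2 features (miR528) in both the copper and the antiviral list, 7 (miR171 and miR319) in both the antiviral and the developmental list, 5 (miR444) in both the silencing and the antiviral list, and 2 (miR164) in both the auxin and the developmental list. The naming rule took up to 10 rising and 10 falling features with the smallest adjusted p for each WDV contrast, up to 5 higher and 5 lower for each cultivar comparison, for each list its most abundant member, its called members and its largest change, and the 10 most abundant features of all.

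Alternatives were RLE scaling, library size alone, no filter on low counts, a mean of 10 or more CPM, an adjusted p of 0.10, limma-voom, DESeq2 1.42.0, a fit of only the groups compared, the 72 lanes as separate samples with the lane number as a replicate block, counts summed per miRNA family, and leaving out each library in turn. Thinning each library to 46951 counts and leaving out the most abundant feature were added after the data had been seen. Correlations of WDV effects between cultivars were compared with the 100 combinations of the 10 splits of each cultivar's 6 libraries, enumerated in place of random draws. The edgeR contrasts were tested on simulated counts with 60 changed features per run in 5 runs. Correlations, permutation tests, lower bounds and counting intervals were not simulated. Folds of 2, 4 and 16 were recovered in 33%, 79% and 91% of cases for WDV in Akteur, 37%, 78% and 96% in Fengyou, 41%, 70% and 93% in Svitava, 72%, 92% and 94% for the mean over cultivars and 9%, 46% and 81% for the difference between cultivars. Of the calls, 2.4% to 4.2% were false. Features were simulated independently of each other, whereas features here may share reads, so these rates may differ in the data. Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, permutation tests and plots.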

Results

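Small RNA libraries from leaves of 3 wheat cultivars, Akteur, Fengyou and Svitava, were compared with and without infection by wheat dwarf virus (WDV), a single-stranded DNA virus spread by leafhoppers. The series concerns small non-coding RNAs in infected wheat and genotypes associated with resistance to the virus, and the groups allow the response to infection to be measured in each cultivar and the cultivars to be compared with each other. Each of the 6 groups held 3 libraries. No mock-inoculated group is labelled, so every WDV contrast also holds any effect of the inoculation procedure. Mean total counts per library in the non-inoculated and infected groups were 89759 ± 30064 and 145156 ± 33962 in Akteur, 68418 ± 28863 and 139291 ± 55155 in Fengyou, and 118551 ± 24157 and 130206 ± 20832 in Svitava (SD, n = 3). The leaves were dominated by ata-miR9863b-3p, of a family known to target NLR immune receptor transcripts in barley and wheat relatives, with 38.3% of all counts and 23.5% to 47.8% per library. It was followed by tae-miR5048-5p (6.88%), tae-miR5200 (6.27%), tae-miR9674b-5p (3.93%) and ata-miR9672-3p (3.46%). The remaining features among the 10 with the highest mean CPM were tae-miR9662a-3p, osa-miR444c.1, ptc-miR6478, tae-miR9774 and gga-miR-7475-5p. Features with animal-style names, 1441 of the 2237, held 3.06% of the counts. No feature carried the name of WDV or of a structural RNA, so WDV levels and RNA breakdown products were not analysed here.

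Infected libraries were sequenced more deeply on average. Over the 3 cultivars, total counts were 92243 ± 32478 without and 138218 ± 34640 with infection (SD, n = 9, exact permutation p = 0.0118, adjusted p = 0.0708 over 12 tests), and 425 ± 34.4 against 493 ± 47.2 features were detected (exact permutation p = 0.007, adjusted p = 0.0708). The 10 most abundant features held 72.6 ± 3.84% against 68.1 ± 5.68% of the counts (exact permutation p = 0.0575, adjusted p = 0.23). None of these differences passed the adjusted threshold. The share of counts under animal-style names, a comparison added after the data had been seen, was 4.78 ± 2.65% without and 2.38 ± 0.50% with infection (SD, n = 9, exact permutation p = 0.00825, adjusted p = 0.066 over 8 tests). Most of these counts were of gga-miR-7475-5p, without which the shares were 1.37 ± 0.82% and 1.09 ± 0.14% in Akteur, 2.56 ± 1.36% and 0.99 ± 0.31% in Fengyou, and 0.91 ± 0.28% and 0.84 ± 0.12% in Svitava (SD, n = 3).

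WDV infection went with a rise of the miRNA families that are known to act on transcripts of copper proteins. These are miR397 (laccases), miR398 (copper/zinc superoxide dismutases), miR408 (plantacyanins and laccases) and miR528, a monocot family that acts on ascorbate oxidase. The 27 features of these families in the table, 9 of them tested, together took 0.841 ± 0.166% of the reads in non-inoculated and 14.4 ± 3.27% in infected Akteur, 0.319 ± 0.162% and 3.02 ± 2.40% in Fengyou, and 0.224 ± 0.062% and 3.40 ± 2.58% in Svitava (SD, n = 3). Averaged over the cultivars, all 9 tested features rose, with a median log2 fold change of 3.80. In the same comparison zma-miR319b-5p, ppe-miR319b, miR827, lus-miR159b and bdi-miR156h-3p rose less steeply, and ata-miR164b-3p fell.

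The mean WDV effect, tested over 9 infected and 9 non-inoculated libraries within their cultivars, passed the adjusted threshold for 22 of 190 features, 19 higher and 3 lower, with 50 at an unadjusted p under 0.05 where 9.5 were expected by chance. Among the copper-protein features, mdm-miR397a rose by 3.80 on the log2 scale (SE 0.42, adjusted p = 1.69e-05), and each of the 9 infected libraries lay above every non-inoculated library of its cultivar. The feature that joins zma-miR398a-3p with tae-miR398 rose by 3.45 (SE 0.42, 9 of 9 libraries), tae-miR397-5p by 3.69 (SE 0.47, 9 of 9), ata-miR398g-5p by 3.52 (SE 0.44, 9 of 9) and ata-miR398f-5p by 3.07 (SE 0.40, 9 of 9). The joined zma-miR528a-5p feature rose by 4.45 (SE 0.58, 8 of 9) and ata-miR408-5p, with 7 counts in all non-inoculated and 563 in all infected libraries, by 5.40 (SE 0.84, 8 of 9). For ata-miR408-5p this mean includes Svitava, where the non-inoculated libraries had 0 counts and only a bound of 15.7-fold can be given. Counts of the joined bdi-miR528-3p feature were 1 against 100, a ratio of 67.1 (95% counting interval 11.8 to 2680), and those of smo-miR408, with 2 in the non-inoculated libraries, gave a ratio of 56.4 (15.4 to 469). Both also passed the test (adjusted p = 0.00407 each, 7 of 9 libraries). Features of 1 family are not independent measurements, and some, such as mdm-miR397a and tae-miR397-5p, are near-identical and may share reads.

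Outside that group, the joined osa-miR827 feature and bdi-miR827-5p, of a family that regulates phosphate transporters, rose by 1.29 (SE 0.23, adjusted p = 0.000651, 8 of 9 libraries) and 1.18 (SE 0.29, adjusted p = 0.00849, 6 of 9). The miR319 features zma-miR319b-5p and ppe-miR319b, of a family that acts on TCP transcription factors, rose by 1.32 (SE 0.25, 7 of 9) and 1.22 (SE 0.25, 8 of 9). Smaller rises were found for lus-miR159b (0.65, SE 0.15, 6 of 9) and bdi-miR156h-3p (0.66, SE 0.16, 6 of 9), whose families act on MYB and SPL transcription factors. Both rises were largest in Akteur. In Akteur, Fengyou and Svitava they were 1.08, 0.17 and 0.69 for lus-miR159b and 1.32, 0.38 and 0.26 for bdi-miR156h-3p. The more abundant miR156 features were not called, with ata-miR156d-3p at -0.12 (SE 0.15, adjusted p = 0.671) and gma-miR156q at -0.25 (SE 0.14, adjusted p = 0.296). Of the features that fell, ata-miR164b-3p, of the family that acts on NAC transcription factors, changed by -0.97 (SE 0.23, adjusted p = 0.00788, 6 of 9), gga-miR-7475-5p by -1.05 (SE 0.29, 3 of 9) and tae-miR9773 by -0.67 (SE 0.19, 7 of 9). The more abundant miR164 feature, osa-miR164d, was not called (-0.32, SE 0.18, adjusted p = 0.296). Targets are given per family, and the arm in a name (5p or 3p) may not be the arm that acts on them. The miR156 and miR164 features not called were named after their values were seen. The naming rule left out osa-miR1432-5p (0.49, SE 0.13, 8 of 9), tae-miR9777 (0.80, SE 0.25) and gra-miR8747, which also rose in the mean and are named here after their values were seen. By cultivar tae-miR9777 stood at 1.83 in Akteur, -0.02 in Fengyou and 0.58 in Svitava, so it did not rise in Fengyou. Counts of gra-miR8747 were 2 without and 65 with infection, a ratio of 21.8 (95% counting interval 5.8 to 184). The feature named bta-miR-2465 had 0 counts in all 9 non-inoculated libraries and 125 counts over the 9 infected libraries, at least 28-fold higher against a floor of 3 counts over the non-inoculated libraries (adjusted p = 7.71e-05, 9 of 9).

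By list, all 9 copper-protein features were called, and 9 adjusted over the list alone (fry adjusted p = 0.00126, adjusted p = 0.0555 with an estimated correlation). The antiviral list was not sorted by whether its families help or hinder a virus. Of its 14 features, 4 rose, and 4 adjusted over the list alone (fry adjusted p = 0.0104, 0.0547 without non-inoculated Akteur library 8, adjusted p = 0.461 with an estimated correlation). These 4 were the pairs of miR319 and miR528 features already named, while the most abundant miR319 feature, bdi-miR319b-3p, stood at 0.62 (SE 0.27, adjusted p = 0.165) and the most abundant miR444 feature, osa-miR444c.1, at -0.18 (SE 0.17). Both miR827 features of the phosphate and sulfate list rose, and 2 adjusted over the list alone (fry adjusted p = 0.00255, adjusted p = 0.174 with an estimated correlation). The 8 auxin features moved downwards on balance (fry adjusted p = 0.00112, adjusted p = 0.174 with an estimated correlation), with 1 called, ata-miR164b-3p, and 2 adjusted over the list alone. Their median was -0.60 in Akteur, -0.23 in Fengyou and -0.09 in Svitava. Of 49 features of families that act on developmental transcription factors, 4 rose and 1 fell, and 5 were called adjusted over the list alone. The mixed test found change in either direction among the members (fry mixed adjusted p = 3.09e-07), but 44 of the 49 were not called. The list did not move 1 way on balance (fry adjusted p = 0.862, camera adjusted p = 0.724 with an estimated correlation).

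The other lists held few calls in the mean effect. Of the silencing list only miR444 features were tested, so its other families were not covered. edgeR called 0 of these 5 features, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. It called 0 of the 13 repeat-related wheat features, with 0 and 0 by the same counts, and the most abundant of them, tae-miR1135, stood at -0.05 (SE 0.12). It called 0 of the 4 NLR-directed features, with 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, and ata-miR9863b-3p stood at -0.12 (SE 0.12). DESeq2 and limma-voom also called 0 in these 3 lists, and the fry adjusted p was 0.698, 0.965 and 0.91 in the order given. Of 26 tested features with animal-style names, which include kshv-miR-K12-6-5p and rrv-miR-rR1-5 named after herpesviruses, bta-miR-2465 rose and gga-miR-7475-5p fell, and 2 were called adjusted over the list alone. Of the 26, 21 were lower and 24 were not called. The mixed test found change in either direction among the members (fry mixed adjusted p = 0.000628), but not on balance in 1 direction (fry adjusted p = 0.698). Across the 4 WDV contrasts fry called 10 of 36 list tests and camera at the preset correlation 9, but camera with an estimated correlation called none. Since fry and camera ask different questions, the last does not undo the calls by fry. The 22 calls, 19 higher and 3 lower, stood at 19 and 9 with RLE scaling and 19 and 8 with library size alone, and at 13 of 116 families when counts were summed per family. Both gga-miR-7475-5p and tae-miR9773 lost their call without infected Akteur library 1, Fengyou libraries 9 (non-inoculated), 1 or 3, or Svitava libraries 6 (non-inoculated), 1 or 3, and tae-miR9773 also without non-inoculated Fengyou library 10 or Svitava libraries 7 (non-inoculated) or 2. The other 17 calls named by the rule held without any 1 library.

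**Figure D1:**
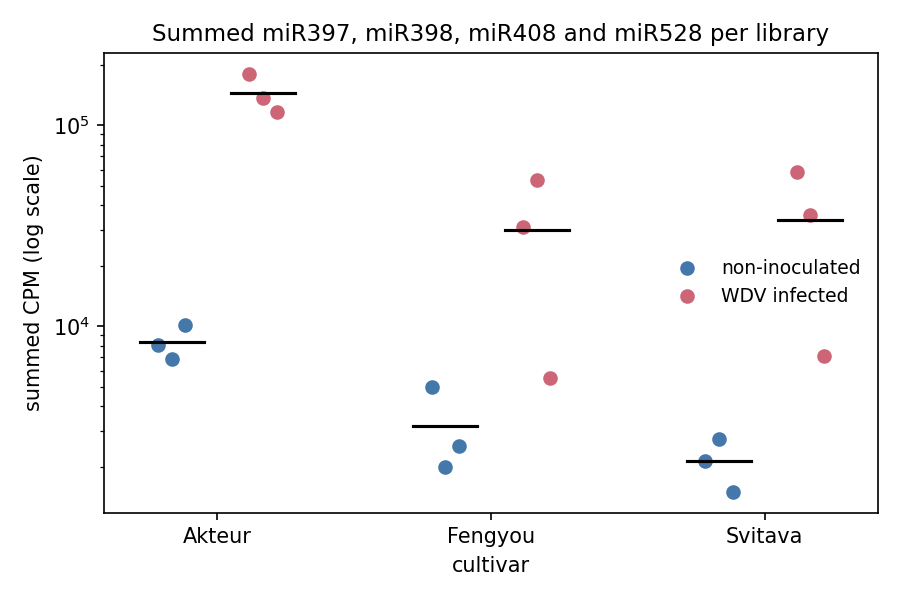
Summed CPM of total counts (log scale) of the 9 tested miR397, miR398, miR408 and miR528 features in each library, by cultivar and treatment, with points for libraries and black lines for group means (n = 3). Infected Akteur libraries lay between 116068 and 180049 CPM, and non-inoculated libraries of all cultivars between 1502 and 10113 CPM.

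In Akteur, 21 of the 190 features differed between infected and non-inoculated libraries, 18 higher and 3 lower, with 44 at an unadjusted p under 0.05. All 9 copper-protein features rose, and 9 adjusted over the list alone, with a median log2 fold change of 4.27. In CPM, mdm-miR397a went from 1802 ± 517 to 34160 ± 21490 and the joined zma-miR398a-3p feature from 3308 ± 886 to 42230 ± 5325 CPM (SD, n = 3). The miR319 features zma-miR319b-5p and ppe-miR319b rose from 371 ± 57.7 to 2087 ± 483 CPM and from 317 ± 96.4 to 1417 ± 170 CPM, and ata-miR164b-3p fell from 226 ± 13 to 50.5 ± 20.8 CPM. In all calls named for Akteur the 3 infected libraries lay beyond the 3 non-inoculated ones, which chance gives for 10% of unchanged features.

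The Akteur log2 fold changes were 4.24 for mdm-miR397a (SE 0.74, adjusted p = 0.00193), 4.50 for zma-miR528a-5p (SE 0.99, adjusted p = 0.0049), 3.67 for zma-miR398a-3p (SE 0.73), 5.47 for ata-miR408-5p (SE 1.05), 2.50 for zma-miR319b-5p (SE 0.43, adjusted p = 0.00193) and 2.17 for ppe-miR319b (SE 0.43). The features osa-miR827, bdi-miR827-5p, bdi-miR156h-3p and lus-miR159b rose by 1.66 (SE 0.39), 1.97 (SE 0.48), 1.32 (SE 0.28) and 1.08 (SE 0.27). These 4 calls, and those of bdi-miR528-3p and smo-miR408, were lost without non-inoculated library 8, which left 15 calls. The features that fell were ata-miR164b-3p (-2.10, SE 0.43, adjusted p = 0.00319), ata-miR5168-5p (-0.89, SE 0.26) and tae-miR5200 (-0.97, SE 0.29), a family that acts on flowering-time genes in Brachypodium, and the last 2 were close to the threshold. The call of tae-miR5200 was lost without Akteur libraries 10 (non-inoculated), 1 or 2, Fengyou libraries 10 (non-inoculated) or 5, or Svitava libraries 6 (non-inoculated) or 2, and that of ata-miR5168-5p without Akteur libraries 1 or 3, Fengyou libraries 9, 10 (non-inoculated), 1, 3 or 5, or Svitava libraries 6, 7 (non-inoculated), 2 or 3. The feature bta-miR-2465 had 0 counts without and 66 with infection, at least 13.7-fold higher. By list, 2 of 2 phosphate features rose (2 adjusted over the list alone, fry adjusted p = 0.00316, adjusted p = 0.174 with an estimated correlation). In the antiviral list 4 of 14 features rose (4 adjusted over the list alone, fry adjusted p = 0.0168, 0.262 without non-inoculated library 8, 0.0695 without infected library 2, adjusted p = 0.461 with an estimated correlation). Without non-inoculated library 8 the NLR list was called (fry adjusted p = 0.0217, against 0.801 with all libraries). Of the auxin features 1 of 8 fell and 4 were called adjusted over the list alone (fry adjusted p = 0.000826, adjusted p = 0.0834 with an estimated correlation). The copper list gave a fry adjusted p of 0.00316 (adjusted p = 0.0834 with an estimated correlation). In the developmental list 4 rose and 1 fell, with 5 adjusted over the list alone, its median (-0.08) and fry's direction (up, adjusted p = 0.941) differed in sign, and its mixed adjusted p was 3.29e-07. Without the filter on low counts 10 features were called. The split of higher and lower calls was 18 and 7 with RLE scaling and 18 and 6 with library size alone.

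In Fengyou, 6 features rose with infection and 0 fell, and all 6 were miR397, miR398 or miR528 features. They were mdm-miR397a, zma-miR398a-3p, zma-miR528a-5p, ata-miR398f-5p, ata-miR398g-5p and tae-miR397-5p. The infected libraries differed widely, with summed CPM of the 9 tested copper-protein features of 31310, 53574 and 5544 in libraries 1, 3 and 5 against 2002 to 4999 in the non-inoculated libraries. The joined zma-miR528a-5p feature stood at 538 ± 568 CPM without and 10820 ± 9020 CPM with infection (SD, n = 3).

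The log2 fold changes of the 6 features ran from 2.95 for zma-miR398a-3p (SE 0.72, adjusted p = 0.0348, 3 of 3 libraries above every non-inoculated library) to 4.27 for zma-miR528a-5p (SE 1.0, adjusted p = 0.0348, 2 of 3). Over the copper list the median was 3.16, or 3.07 with the 2 features at 0 in non-inoculated libraries set to their lower bounds. Adjusted over the list alone 8 of 9 were called, and fry gave an adjusted p of 0.0542 (adjusted p = 0.108 with an estimated correlation). The 2 miR827 features, 1.31 (SE 0.40) and 1.54 (SE 0.53), passed adjusted over the list alone but not over all features (fry adjusted p = 0.0419, adjusted p = 0.174 with an estimated correlation). The fry call of that list was lost without Fengyou libraries 9, 10, 11 (non-inoculated), 1 or 3, infected Akteur library 2 or non-inoculated Svitava library 6 (adjusted p 0.0522 to 0.125). The copper list was called without infected Fengyou library 5 (adjusted p = 0.00551), Akteur libraries 9, 10 (non-inoculated), 1 or 3, or infected Svitava libraries 1 or 3 (0.024 to 0.0496), and the auxin list (0.0684 with all libraries) without infected Fengyou library 5 (0.0319) or infected Svitava library 2 (0.0358). The count of 0 lower calls was from edgeR, with 24 features in either direction at an unadjusted p under 0.05, and DESeq2 called 6 features in all. Features with animal-style names took 6.92 ± 0.60% of the reads without and 2.82 ± 0.50% with infection (SD, n = 3). Of the 26 tested, 22 were lower, 0 were called in edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone and 8 at an unadjusted p under 0.05, with a median log2 fold change of -0.99. The list was called by camera at the preset correlation (adjusted p = 0.00039, adjusted p = 0.301 with an estimated correlation) and by fry for change in either direction (mixed adjusted p = 0.0452), but not by fry for 1 direction (adjusted p = 0.217). The count of 6 calls changed under many settings. The count was 0 with limma-voom, with a mean of 10 or more CPM, with only the 2 Fengyou groups fitted, and without non-inoculated Fengyou libraries 9, 10 or 11, infected Fengyou library 1, Akteur libraries 8 (non-inoculated), 1, 2 or 3, or Svitava libraries 6, 7, 8 (non-inoculated) or 2, and it was 1 without infected Fengyou library 3, 2 without the filter, 3 when summed per family and 10 at an adjusted p of 0.10.

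In Svitava, 8 features rose and 0 fell. Of the 9 copper-protein features 7 were among them, and the other feature called was bta-miR-2465. The joined zma-miR528a-5p feature went from 277 ± 92.4 to 6729 ± 5921 CPM and mdm-miR397a from 433 ± 68.1 to 7118 ± 4903 CPM (SD, n = 3). Summed copper-protein CPM was 58766, 35797 and 7141 in infected libraries 1, 2 and 3 against 1502 to 2740 in the non-inoculated ones.

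The log2 fold changes were 4.03 for mdm-miR397a (SE 0.74, adjusted p = 0.00747), 3.72 for zma-miR398a-3p (SE 0.74), 4.18 for tae-miR397-5p (SE 0.84), 4.59 for zma-miR528a-5p (SE 1.02), 3.23 for ata-miR398g-5p (SE 0.76) and 2.77 for ata-miR398f-5p (SE 0.67), with 3 of 3 libraries above every non-inoculated library in each. Counts of ata-miR408-5p were 0 without and 55 with infection, at least 15.7-fold higher (adjusted p = 0.0351), and those of bta-miR-2465 were 0 and 36, at least 10.3-fold higher (adjusted p = 0.00969). The copper list had a median of 4.18, or 3.72 with the 3 features at 0 set to their lower bounds, 9 of 9 called adjusted over the list alone, and a fry adjusted p of 0.0182 (adjusted p = 0.0555 with an estimated correlation), which was 0.0536 to 0.0668 without libraries 6, 7, 8 (non-inoculated), 1 or 2. The antiviral list (fry adjusted p = 0.217) was called without infected library 3 (0.0287). The miR827 features stood at 0.90 (SE 0.38, adjusted p = 0.416, 3 of 3 libraries) for osa-miR827 and 0.03 (SE 0.47, 0 of 3) for bdi-miR827-5p (fry adjusted p = 0.428), and 5 of the 8 auxin features were lower (fry adjusted p = 0.82). The 0 lower calls were from edgeR, with 20 features in either direction at an unadjusted p under 0.05, and DESeq2 called 8 features and limma-voom 3. The count was 0 with only the 2 Svitava groups fitted and without non-inoculated libraries 6 or 7 or infected library 1, 2 without non-inoculated library 8, 5 without infected library 2, 3 without the filter, and 4 with a mean of 10 or more CPM or when summed per family.

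The 6 features called in Fengyou were called in all 3 cultivars. Of the features that rose, Akteur and Fengyou shared 6 where 0.57 were expected of independent lists, Akteur and Svitava shared 8 (0.76 expected), and Fengyou and Svitava shared 6 (0.25 expected). The cultivars had no libraries in common in these contrasts, but all 18 libraries were fitted together with shared dispersions. The 6 features called in all cultivars are also miR397, miR398 and miR528 features, some of which may share reads. The lists are therefore not independent, and the expected numbers are only a rough scale. Across the 190 features, which are not independent replicates, the WDV effects correlated with Pearson's r of 0.71 between Akteur and Fengyou, 0.72 between Akteur and Svitava, and 0.70 between Fengyou and Svitava (permutation p = 0.02, 0.01 and 0.03 over 100 enumerated splits, adjusted p = 0.03 each over 3 tests). Spearman's rho was 0.31, 0.35 and 0.39 (permutation p = 0.17, 0.1 and 0.03, adjusted p = 0.17, 0.15 and 0.09). The highest absolute r of any other split was 0.77, 0.69 and 0.72. Without the 9 copper-protein features r was 0.49, 0.49 and 0.47 and rho 0.20, 0.25 and 0.30, and these values were not compared with other splits. The 181 features left still held bta-miR-2465 and gra-miR8747, with 0 and 2 non-inoculated counts. Their log2 fold changes in Akteur, Fengyou and Svitava were 7.24, 5.64 and 6.29, and 5.87, 5.66 and 2.80. Such extreme values can weigh heavily on r, and r without them was not computed. Without the filter on low counts r was 0.09, 0.11 and 0.08, and between Akteur and Fengyou it was 0.40 without non-inoculated Akteur library 9.

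No feature passed the test of whether the WDV effect differed between cultivars. edgeR called 0 of 190, with 15 at an unadjusted p under 0.05 and a smallest adjusted p of 0.486, and DESeq2 and limma-voom also called 0. Among the features with the smallest unadjusted p, zma-miR319b-5p had log2 fold changes of 2.50 (SE 0.43) in Akteur, 0.56 (SE 0.45) in Fengyou and 0.90 (SE 0.43) in Svitava (p = 0.0114 across features in edgeR, adjusted p = 0.486). For ata-miR164b-3p they were -2.10 (SE 0.43), -0.25 (SE 0.41) and -0.57 (SE 0.37), with an adjusted p of 0.486. In simulated data, differences of 2-fold and 4-fold in the response were recovered in 9% and 46% of cases, so differences of these sizes could be missed. Without non-inoculated Akteur library 9 the features mmu-miR-5110 and dme-miR-14-5p were called (adjusted p = 0.0213 each), and osa-miR5076 was called without infected Fengyou library 3 (adjusted p = 0.0383) and without the filter (adjusted p = 0.0323). These 3 features were named after their values were seen.

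**Figure D2:**
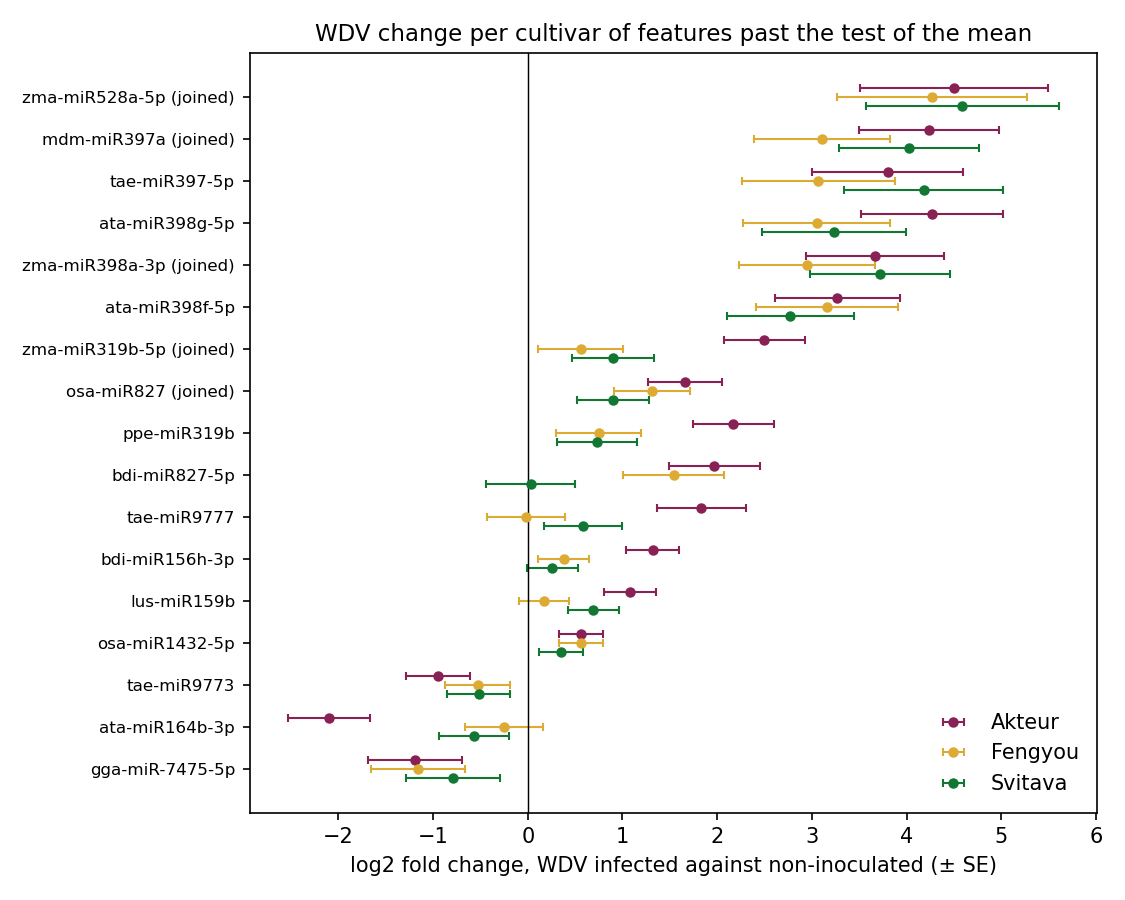
Log2 fold change of infected against non-inoculated libraries, with SE bars, in Akteur, Fengyou and Svitava (n = 3 against 3 each), for 17 of the 22 features past the test of the mean effect, leaving out 5 features with 0 to 3 counts in a non-inoculated group. The miR397, miR398 and miR528 features lay between 2.77 and 4.59 in all 3 cultivars, and names marked as joined carry further miRNA names.

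The cultivars were then compared within each treatment. Without inoculation, Fengyou and Akteur differed in 13 features, 8 higher and 5 lower in Fengyou, with 35 at an unadjusted p under 0.05. The wheat miRNA tae-miR9661-5p stood at 917 ± 237 CPM in Fengyou and 139 ± 79.9 CPM in Akteur, and tae-miR5384-3p at 269 ± 38.4 against 57.4 ± 32.2 CPM. Lower in Fengyou were tae-miR9663-5p, with 505 ± 87.4 against 1484 ± 132 CPM, and tae-miR9664-3p, with 222 ± 101 against 892 ± 268 CPM (SD, n = 3). The log2 differences were 2.68 (SE 0.43, adjusted p = 0.00198), 2.18 (SE 0.40, adjusted p = 0.00445), -1.56 (SE 0.32, adjusted p = 0.00807) and -2.06 (SE 0.51, adjusted p = 0.02). Also higher in Fengyou were ath-miR8175 (1.43, SE 0.31), zma-miR159d-5p (1.40, SE 0.32) and lus-miR159b (1.10, SE 0.27), and lower were osa-miR5071 (-0.97, SE 0.22) and gma-miR396e (-0.87, SE 0.23), of a family that acts on GRF transcription factors. In each of these 9 features the 3 libraries of a cultivar lay apart from the 3 of the other. The naming rule took 10 features in this comparison, of which these 9 are described. edgeR called 0 of the 9 copper-protein features, with 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Their median log2 difference was -1.62, lower in Fengyou. The count of 13 was 3 without non-inoculated Akteur library 8 or 10, 4 without Fengyou library 10, 7 without Fengyou library 11 and 5 without the filter. With library size alone the split was 10 higher and 3 lower, and the median difference of all features moved from -0.11 to 0.00.

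Non-inoculated Svitava differed from Akteur in 5 features, with 38 at an unadjusted p under 0.05. Lower in Svitava was tae-miR9663-5p, which had 1484 ± 132 CPM in Akteur (log2 difference -1.89, SE 0.31, adjusted p = 0.00276), and higher was tae-miR9653a-3p, annotated to target NLR genes, at 2799 ± 869 against 1022 ± 242 CPM (1.45, SE 0.30, adjusted p = 0.0156). The others were tae-miR9661-5p (1.77, SE 0.43), ath-miR8175 (1.33, SE 0.31) and ame-miR-9880 (-1.38, SE 0.32), each with an adjusted p of 0.026 and all 3 libraries apart. Of the 9 copper-protein features 0 were called in edgeR (4 at an unadjusted p under 0.05, 0 in limma-voom, 2 in DESeq2), but 2 were lower in Svitava adjusted over the list alone. Their median log2 difference was -2.06. The count of 5 was 12 in DESeq2, 9 with only these groups fitted and 3 with library size alone or without the filter. It was 1 without Akteur library 8 or Svitava library 8, 2 without Svitava library 7, 3 without Akteur library 9 and 8 without infected Fengyou library 5.

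Between non-inoculated Fengyou and Svitava 4 features differed, all higher in Fengyou, with 34 at an unadjusted p under 0.05. They were tae-miR5384-3p, at 269 ± 38.4 against 88.2 ± 6.20 CPM (1.59, SE 0.37, adjusted p = 0.031), bdi-miR7757-5p.1 (1.34, SE 0.28, adjusted p = 0.031), lus-miR159b (1.17, SE 0.27, adjusted p = 0.031) and ame-miR-9880 (1.34, SE 0.32, adjusted p = 0.0311), with all 3 libraries of the cultivars apart in each. The calls were weakly held. DESeq2 called 0 and limma-voom 4, and the count was 0 without the filter, with a mean of 10 or more CPM, with only these groups fitted, and without Fengyou libraries 10, 11 (non-inoculated) or 5, Svitava libraries 6, 8 (non-inoculated), 1, 2 or 3, or infected Akteur library 2. It was 2 without Akteur library 8 or Svitava library 7, 7 without Akteur library 9 and 1 after thinning.

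Under infection, Fengyou and Akteur differed in 21 features, 10 higher and 11 lower in Fengyou, with 58 at an unadjusted p under 0.05. The contrast of tae-miR5384-3p (338 ± 8.43 against 48.5 ± 17.4 CPM) and tae-miR9661-5p (1254 ± 273 against 224 ± 111 CPM) lay in the same direction as without inoculation, as did those of tae-miR9664-3p (84.9 ± 63.0 against 898 ± 579 CPM) and tae-miR9663-5p (367 ± 17.7 against 1391 ± 441 CPM). The miR319 features zma-miR319b-5p and ppe-miR319b were lower in infected Fengyou, with zma-miR319b-5p at 258 ± 129 against 2087 ± 483 CPM (SD, n = 3). Log2 differences were 2.74 (SE 0.37, adjusted p = 0.000257) for tae-miR5384-3p, 2.46 (SE 0.40) for tae-miR9661-5p, -3.48 (SE 0.53) for tae-miR9664-3p, -1.92 (SE 0.31) for tae-miR9663-5p, -2.99 (SE 0.43, adjusted p = 0.000257) for zma-miR319b-5p and -2.31 (SE 0.42) for ppe-miR319b, while the most abundant miR319 feature, bdi-miR319b-3p, stood at -0.16 (SE 0.46, adjusted p = 0.835). Further higher features were ata-miR5168-5p (1.32, SE 0.26), tae-miR167c-5p (1.19, SE 0.24) and gma-miR393h (0.98, SE 0.23), the last 2 from families that act on auxin response factors and auxin receptors, and ata-miR171a-3p was lower (-0.85, SE 0.20). All 3 libraries of the cultivars lay apart in each. Of the copper-protein features 4 of 9 were lower in infected Fengyou, and 9 adjusted over the list alone. Their median was -2.54, against -1.62 without inoculation. Of the auxin features 3 of 8 were higher, and 4 adjusted over the list alone. The calls numbered 12 without infected Akteur library 1, 11 without the filter and 32 in limma-voom.

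Infected Svitava and Akteur differed most, in 37 features, 13 higher and 24 lower in Svitava, with 66 at an unadjusted p under 0.05. Lower in Svitava were tae-miR9663-5p (335 ± 92.2 against 1391 ± 441 CPM) and zma-miR319b-5p (392 ± 102 against 2087 ± 483 CPM), and higher were ata-miR164b-3p (246 ± 33.3 against 50.5 ± 20.8 CPM) and tae-miR9653a-3p (2567 ± 301 against 862 ± 226 CPM; SD, n = 3). Log2 differences were -2.06 (SE 0.31, adjusted p = 0.00106), -2.41 (SE 0.42, adjusted p = 0.00156), 2.22 (SE 0.42, adjusted p = 0.00217) and 1.58 (SE 0.30, adjusted p = 0.00217), with all 3 libraries of the cultivars apart. The other features named were tae-miR5175-5p (-1.38, SE 0.23), bdi-miR7757-5p.1 (-1.42, SE 0.28), osa-miR6253 (-1.92, SE 0.41), zma-miR159d-5p (1.66, SE 0.31), ata-miR167d-3p (1.76, SE 0.37) and osa-miR166b-5p (0.77, SE 0.18). Of the copper-protein features 5 of 9 were lower in Svitava, and 8 adjusted over the list alone. Their median was -2.38, against -2.06 without inoculation. Of the auxin features 4 of 8 were higher, and 4 adjusted over the list alone. In the developmental list 6 were higher and 9 lower, with 15 of 49 adjusted over the list alone. The median difference of all 190 features was -0.25 with TMM and -0.09 with library size alone, under which the split was 21 higher and 22 lower. The calls numbered 17, 10 and 11 without infected Svitava libraries 1, 2 and 3, 14 without the filter, 22 with a mean of 10 or more CPM and 20 when summed per family.

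Infected Fengyou and Svitava differed in 9 features, 5 higher and 4 lower in Fengyou, with 38 at an unadjusted p under 0.05. Lower in Fengyou was tae-miR9664-3p, at 84.9 ± 63.0 CPM (log2 difference -3.79, SE 0.54, adjusted p = 0.000396), together with ata-miR171a-3p (-0.92, SE 0.20), tae-miR1847-5p (-1.70, SE 0.39) and ata-miR167d-3p (-1.53, SE 0.36). Higher were tae-miR5384-3p, at 338 ± 8.43 against 94.8 ± 27.3 CPM (1.81, SE 0.35, adjusted p = 0.00786), tae-miR9661-5p (1.75, SE 0.39), gma-miR393h (0.98, SE 0.23) and bdi-miR7757-5p.1 (1.07, SE 0.28). Also called was ata-miR169b-3p, which had 60 counts in infected Fengyou and 0 in infected Svitava, at least 20.4-fold higher (adjusted p = 0.0306). All 3 libraries of the cultivars lay apart in each. edgeR, DESeq2 and limma-voom called 0 of the 9 copper-protein features, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. With library size alone the split was 4 higher and 5 lower. The calls numbered 5, 3 and 1 without infected Svitava libraries 1, 2 and 3, 4 without infected Fengyou library 5 or without the filter, 19 with only these groups fitted and 3 after thinning.

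**Figure D3:**
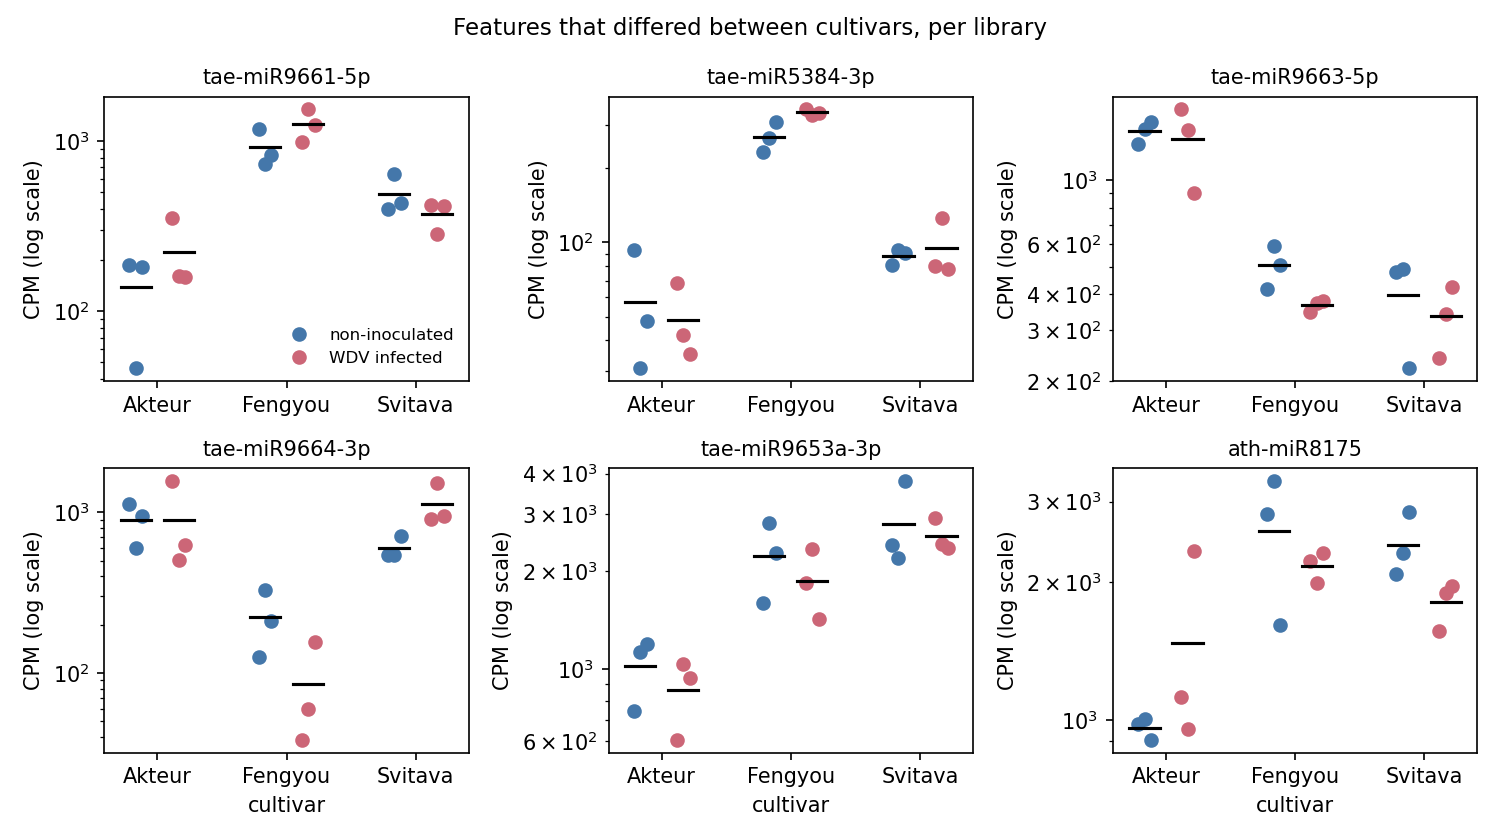
CPM (log scale) per library of 6 features that differed between cultivars, by cultivar and treatment, with points for libraries and black lines for group means (n = 3). Akteur libraries held the least tae-miR9661-5p and the most tae-miR9663-5p (group means 139 and 1484 CPM without inoculation), and Fengyou the most tae-miR5384-3p and the least tae-miR9664-3p (269 and 222 CPM).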

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

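The tests in this part were chosen only after the result was seen. A signal outside the tested features was found for aca-miR-1805-5p, which is named after a lizard and had too few counts to be tested. It had 35 counts over the 9 infected libraries, at least 1 in each, and 0 in the 9 non-inoculated libraries, where 23.4 were expected from the total counts. The difference was not tested with the other features, and the smallest p that an exact permutation of 9 against 9 libraries within cultivars can give is 0.00025.

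Together with bta-miR-2465 and gra-miR8747 it makes 3 features counted in 8 or more infected and at most 1 non-inoculated library, while 0 features showed the reverse. Deeper sequencing of the infected libraries does not explain this, since 83.4 counts of bta-miR-2465 were expected in the non-inoculated libraries at its rate in the infected ones and 0 were found. For bta-miR-2465 and aca-miR-1805-5p, reads from the animals whose names they carry were examined through the other 67 features with the same 2 species codes. Of their 1460 counts 40.3% fell in non-inoculated libraries, which held 40.0% of all counts (55.3% of 338 counts without bta-miR-2478, the largest of them). Those features thus did not follow infection. The test rests mostly on bta-miR-2478, and whether these are animal reads is unknown. Reads from other animals were not tested. The third, gra-miR8747, carries a plant name and was not part of that test. Small RNAs of the virus that match these names by chance could give such a pattern, as could wheat small RNAs made only on infection, but the 3 features alone do not separate these and the sequences were not used here.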

How the results depend on the processing

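Alternatives were set before the data were examined, except thinning to the lowest depth and leaving out the most abundant feature, which were chosen only after the result was seen. Of 100 named calls, 39 kept their side of the threshold under every setting and 0 reversed. The cause of the changed values was not tested, except that fewer features (116 families, 150 after thinning) or a larger set (2237 without the filter, 292 with a mean of 10 CPM) were tested by construction, against 190.

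Counts of calls against the main value were as follows. Akteur WDV 21: 10 without the filter, 15 to 27 without 1 library. Fengyou WDV 6: 2 without the filter, 0 with a mean of 10 CPM, limma-voom or only the groups compared, 10 at an adjusted p of 0.10, 3 by family, 0 to 9 without 1 library. Svitava WDV 8: 3 without the filter, 4 with a mean of 10 CPM, 3 with limma-voom, 0 with only the groups compared, 4 by family, 0 to 10 without 1 library. Mean WDV 22: 13 by family, 18 to 27 without 1 library. Difference between cultivars 0: 1 without the filter, 0 to 2 without 1 library. Fengyou against Akteur, non-inoculated, 13: 5 without the filter, 3 to 16 without 1 library. Svitava against Akteur, non-inoculated, 5: 3 with library size alone, 3 without the filter, 9 at an adjusted p of 0.10, 12 with DESeq2, 9 with only the groups compared, 1 to 8 without 1 library. Fengyou against Svitava, non-inoculated, 4: 0 without the filter, with a mean of 10 CPM, DESeq2 or only the groups compared, 2 by family, 1 thinned, 0 to 7 without 1 library. Fengyou against Akteur, infected, 21: 11 without the filter, 43 at an adjusted p of 0.10, 32 with limma-voom, 12 to 23 without 1 library. Svitava against Akteur, infected, 37: 14 without the filter, 22 with a mean of 10 CPM, 62 at an adjusted p of 0.10, 20 by family, 10 to 45 without 1 library. Fengyou against Svitava, infected, 9: 4 without the filter, 19 with only the groups compared, 3 thinned, 1 to 11 without 1 library. Correlations of WDV effects were 0.09, 0.11 and 0.08 without the filter for Akteur with Fengyou, Akteur with Svitava and Fengyou with Svitava, 0.57 and 0.51 with a mean of 10 CPM for the last 2, and 0.40 to 0.71 without 1 library for the first. List calls went from 10 with fry to 0 with camera at an estimated correlation. The p of the share of the 10 most abundant features was 0.0318 to 0.105 without 1 library.

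With the 72 lanes as samples and the lane number as a replicate block, calls among the 119 features tested there, in the order above, were 51, 35, 34, 52, 43, 46, 57, 40, 68, 76 and 49. Lanes of 1 library were then counted as replicates, and the cause of the changed counts was not tested separately. Lanes of the same number did not deviate together (mean r 0.00, with 19.3% of pairs over 0.1).

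Features not called changed sign in the mean effect as follows. ata-miR9863b-3p from -0.12 to 0.02, ptc-miR6478 from -0.07 to 0.06 (-0.19 to 0.05 without 1 library), tae-miR1135 from -0.05 to 0.09 (-0.16 to 0.02) and tae-miR9774 from -0.02 to 0.11 (-0.24 to 0.21) without the filter. With limma-voom tae-miR9774 was 0.13 and ssp-miR444b.1 went from -0.25 to 0.10 (-0.52 to 0.26), and tae-miR9774 was 0.01 with the block. tae-miR5048-5p, at 0.18, was -0.02 to 0.30 without 1 library, and tae-miR9662a-3p, at 0.07, was -0.05 thinned (-0.04 to 0.18). tae-miR9674b-5p, at 0.02, was -0.02 with RLE, 0.00 with library size, -0.03 with DESeq2, -0.11 thinned, -0.02 without the most abundant feature and -0.09 to 0.18 without 1 library.

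Lists not called changed direction, given as adjusted p. NLR: Akteur 0.801 (0.0217 to 0.942 without 1 library), Svitava 0.82 (0.472 to 0.996), mean 0.91 (camera 0.847, estimated 0.909, RLE 0.651, library size 0.851, 0.238 to 0.982). Silencing: Akteur 0.775 (0.262 to 0.916), Fengyou 0.894 (0.695 to 0.996), Svitava 0.82 (0.567 to 0.996). Auxin: Svitava 0.82 (library size 0.924, 0.533 to 0.982). Developmental: Akteur 0.941 (camera 0.354, estimated 0.724, RLE 0.54, library size 0.851, 0.238 to 0.996), Fengyou 0.862 (RLE 0.963, library size 0.66, 0.358 to 0.996), Svitava 0.698 (0.308 to 0.996), mean 0.862 (0.286 to 0.996). Animal-style: Akteur 0.839 (camera 0.846, estimated 0.921, 0.152 to 0.991). Repeat-related: Akteur 0.854 (camera 0.84, estimated 0.909, 0.104 to 0.968), Fengyou 0.91 (library size 0.851, 0.556 to 0.996), Svitava 0.753 (0.318 to 0.996), mean 0.965 (0.358 to 0.996).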

Other observations

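The tests in this part were chosen only after the result was seen, apart from the splits of the libraries. Alternative explanations were set against the rise of the copper-protein miRNAs with infection, which had a median log2 fold change of 3.80. With all libraries thinned to the lowest total the median was 3.63 (7 of 8 tested features called), so most calls did not need the extra depth. Thinning keeps the proportions within a library, so it cannot test whether these proportions were linked to depth in another way. Without the most abundant feature the median was 3.74, so a shift caused by that feature does not account for the rise. With the sheet number as a linear covariate the median was 3.81 (9 of 9 called). Sheet numbers 8 to 14 were all infected libraries, so an effect of the middle of the sheet cannot be told apart from infection. The rise could be a response to infection, but no mock-inoculated group is labelled. Effects of the inoculation procedure therefore cannot be told apart from those of the virus. Copper supply and the age of the leaves were not measured here.

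Whether the copper-protein miRNAs followed the extent of infection was tested over the 9 infected libraries, with the summed features counted almost only in infected libraries as a stand-in. Within cultivars the log2 values gave an r of 0.67 (exact permutation p = 0.255, Bonferroni-adjusted p = 0.509 over 2 tests), a rho of 0.57 (exact permutation p = 0.329), an r of -0.62 without Fengyou library 5 and Svitava library 3, and an r of 0.90 with bta-miR-2465 alone as the stand-in. The copper-protein values also followed library totals (r 0.83, exact permutation p = 0.00926, Bonferroni-adjusted p = 0.0185), so the relation remains open.

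Other splits of the libraries of 2 groups into 3 against 3 number only 10, too few for a share under 0.05, and in each of the 9 comparisons of 3 against 3 only 1 split, the real one, gave as many calls. The real and the highest other counts were 21 and 2 for WDV in Akteur, 6 and 0 in Fengyou, 8 and 0 in Svitava, 13 and 6 for Fengyou against Akteur without inoculation, 5 and 1 for Svitava against Akteur, and 4 and 0 for Fengyou against Svitava. Under infection they were 21 and 0, 37 and 0, and 9 and 1 in the same order. For the mean effect 1 of 100 splits gave as many calls (22, highest other 4), which leaves chance as an unlikely source. For the difference between cultivars the real count was 0 (highest other 19). All 100 splits then give as many by construction, so the splits say nothing about chance there.

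Some features with animal-style names were concentrated in single libraries. Of 441 counts of the joined crm-miR-71-5p feature 141 were in infected Svitava library 2, and of 87 counts of bta-miR-2304 77 were in non-inoculated Svitava library 8. Of 2196 counts of bmo-miR-3423 796 were in non-inoculated Fengyou library 10.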
